A study of Mus musculus with 2 samples.

How the data were processed

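H3K36me3 was measured by chromatin immunoprecipitation and sequencing in facial prominences of mouse embryos at embryonic day 13.5. Both samples belong to 1 group and are biological replicates 1 and 2, numbered per the labels. The labels give them separate tissue samples but the same donor identifier, so how far the spread between them reflects separate pools of embryos is not known, and n = 2 throughout.

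The authors deposited 4 peak lists on the mm10 build in the narrowPeak format, which gives 1 line per peak. Per the deposited descriptions of the files, the list of each replicate was made from the filtered alignments of its 2 technical replicates together. The list of both replicates, called pooled here, was made from all alignments. The replicated list was derived from the other 3 lists. Replicate 1 and the pooled list used 2 further files and replicate 2 used 1, of a kind that those descriptions do not state. The aligner, peak caller, control, thresholds and replication rule are not given in the sources used here. Each peak carries the authors' enrichment value, a ratio or fold enrichment (column 7 of the deposited lists). It also carries the −log10 of its p-value and of its q-value (columns 8 and 9 of the deposited lists, made by the authors' peak caller). The smallest deposited −log10 p was 2.00 in replicate 1 and 2.03 in replicate 2. A q-value of 0.01 or lower was held by 94.1% of peaks in replicate 1 and 87.8% in replicate 2. Enrichment was used to describe, rank or filter peaks within a list, and for an enrichment load computed within each list. Sequencing depth is unknown, since the lists give no read counts, so no counting interval or detection limit can be given. How far depth accounts for the difference between the replicates in peak number and coverage was therefore not measured.

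The reference was the GRCm38 assembly, the same build as mm10, with the GENCODE M21 annotation (Ensembl 96). No peak extended past the end of a chromosome of this reference. Gene-level values were restricted to the 19 autosomes, X and Y. Peaks on other contigs (34 in replicate 1 and 18 in replicate 2) were left out of them. Every base was assigned to 1 territory, in the order promoter (1 kb either side of the start of a protein-coding gene), exon, intron, 5 kb after a gene end, other annotated gene and intergenic. Unsequenced gaps were left out. Coverage of a gene is the percentage of bases from its annotated start to its end that lie in peaks, computed for each replicate list. Overlapping genes share bases, and peaks carry no strand. Protein-coding genes of 2 kb or longer were measured, and a gene was called marked at a coverage of at least 10% in each replicate list. The profile along genes used genes of 10 kb or longer. The enrichment load of a gene is the sum over its peak bases of the authors' enrichment, divided by gene length.

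With a single group of 2 samples no comparison between conditions and no test across genes or peaks was made, since genes and peaks are not replicates. Differences are set against the SD of the replicate lists. Peak lists were compared by overlap (at least 50% of the shorter peak) and by the Jaccard index of covered bases, beside 100 random placements of replicate 2 peaks on the same chromosome. For 25 gene lists, the median of the mean coverage was placed among 10000 random lists of the same size matched on deciles of gene length. A list was said to lie outside the random range when its median fell in the upper or lower 2.5%. This describes these libraries and is not a test. The lists covered facial mesenchyme transcription factors, Hox genes, cartilage and bone, extracellular matrix, epithelium, neurons, glia, skeletal muscle, endothelium, red blood cells, macrophages, housekeeping genes, liver, germ cells, photoreceptors, chemoreceptors, zinc finger genes, replication-dependent histones, clustered protocadherins, the H3K36 methylation machinery, the cell cycle, facial signalling, clefts and craniofacial syndromes, imprinted genes and X-linked genes. The X-linked list was made of genes chosen as escaping X inactivation and of controls. The imprinted and X-linked lists also hold non-coding genes, which were not measured here as list members.

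The gene lists, the comparisons of the report, the first 47 alternatives and the rule for named genes were fixed before the data were examined. The closing section names the tests and alternatives chosen later. The rule named up to 4 members with the highest and 2 with the lowest mean coverage of each list, and the 3 highest members of each family defined by its symbols. It also named the 10 genes of 5 kb or longer with the highest load, and the 5 such genes with the largest coverage difference between replicates in each direction. The 5 longest stretches of replicated peaks merged over gaps of up to 3 kb were named, as were the 5 longest of these farther than 10 kb from any annotated gene. Dlx5, Msx1, Prrx1, Twist1, Satb2, Irf6, Hoxa2, Setd2 and Nsd1 were named in any case. Ties went in alphabetical order. Where several members tied at no coverage, the text names only some of them.

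The alternatives were a stricter threshold (q of 0.01 or lower, or an enrichment of at least 2), other overlap rules, equal numbers of the strongest peaks, random placement within annotated genes, and the replicated or pooled list in place of the replicate lists. Gene length and coverage limits, gene bodies without the first 1 kb, unmatched random lists and genes without overlapping neighbours were tried too, with others listed in the closing section, and each replicate was left out in turn. Another 3 alternatives were added after the data were seen.

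Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and matplotlib 3.10.9 for the figures. The code was tested on simulated data. Interval arithmetic gave no wrong value in 1876 comparisons with arrays of single bases. In the simulation of marked genes, over 15920 genes that overlap no other, all 200 genes given high coverage were called and no other gene was. Because those 200 genes were set to high coverage, this outcome does not give the accuracy of the call near the coverage limit. In the measured lists, 800 genes passed that limit in replicate 1 only and 39 in replicate 2 only. In the simulation of gene list coverage, 6.50% of 200 random lists fell outside the random range by chance. Every simulated gene had some coverage, whereas 41.9% of the measured genes had no peak base in either list. The rate therefore need not hold for the measured lists, whose random medians were often 0.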

Results

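Trimethylation of lysine 36 of histone H3 (H3K36me3), a chromatin mark laid down over the bodies of transcribed genes, was mapped by chromatin immunoprecipitation and sequencing in the facial prominences of mouse embryos. The facial prominences are the paired tissue swellings that fuse to form the face, made of neural crest-derived mesenchyme under a surface ectoderm. The tissue was taken at embryonic day 13.5 from embryos of both sexes, pooled, of strain B6NCrl. There was 1 group with 2 biological replicates, each sequenced as 2 technical replicates that were combined before peaks were called. No second tissue, stage or treatment was available here, so the results below describe where the mark lay and how far both replicates shared it. Replicate 1 had 198711 peaks covering 129.8 Mb, or 4.90% of the sequenced chromosomes, and replicate 2 had 170828 peaks covering 104.1 Mb, or 3.93%. Sequencing depth is unknown, because the peak lists hold no read counts. Values with ± are means and SDs over the replicate lists (n = 2). For the median coverage of a gene list, the value is the median of its members' mean coverage. The SD beside it is that of the medians in the replicate lists.

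How far the biological replicates shared their peaks was asked first. A peak was counted as shared when at least 50% of the shorter of the overlapping peaks was covered. By this rule 61.1% of replicate 1 peaks (121378) had a partner in replicate 2, and 81.2% of replicate 2 peaks (138646) had a partner in replicate 1. The covered bases overlapped with a Jaccard index of 59.5%, against 2.48% when replicate 2 peaks were placed at random on the same chromosomes. Random placement gave a partner to 6.66% of replicate 2 peaks, with 6.83% as the highest of 100 placements, and to 13.1% when the peaks were placed only inside annotated genes. Sharing was most frequent among the strongest peaks. The enrichment value of a peak is the authors', and it is used here only within a list. In the lowest decile of enrichment 29.1% of replicate 1 peaks were shared, and in the highest decile 99.4%. The corresponding values for replicate 2 were 66.9% and 99.7%, with the lowest value, 62.9%, in decile 2. Unshared replicate 1 peaks were narrow, with a median width of 260 bp against 566 bp for shared ones. In replicate 2 the widths were 247 and 449 bp. Width and enrichment were not separated, and random placement was not run by decile. Requiring 50% of both peaks lowered the mean share over both directions from 71.1% to 43.3%.

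**Figure D1:**
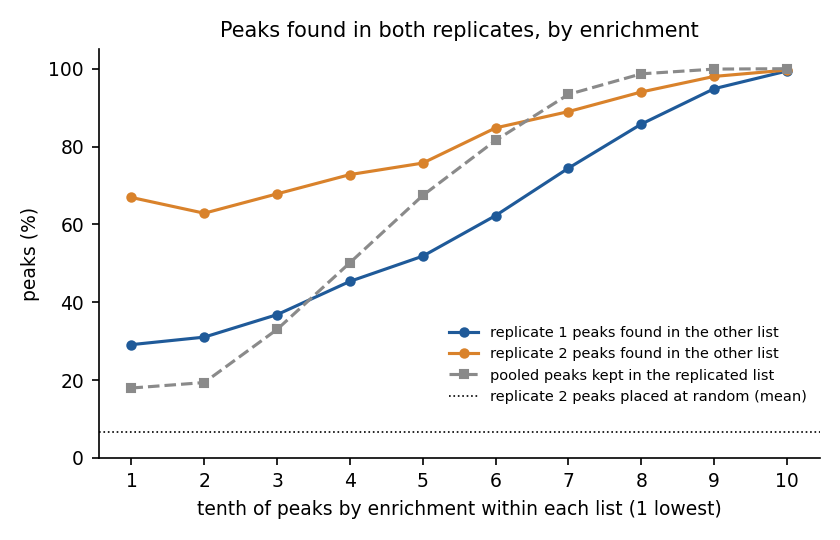
Share of peaks (%) found in the other replicate list (circles), and of pooled peaks kept in the replicated list (squares), by decile of enrichment within each list. The dotted line is the mean share after random placement of all replicate 2 peaks, not split by decile (6.66%). Sharing reached 99.4% and 99.7% in the highest decile of replicates 1 and 2.

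The peak list made from both replicates together held 194906 peaks, of which 128919 (66.1%) were carried unchanged into the authors' replicated list. Retention was 17.9% in the lowest decile of enrichment and 100% in the highest. All 107305 pooled peaks with a partner in both replicate lists were kept, as were 21614 of the 87601 others (24.7%). The strongest pooled peak had an enrichment of 19.54 and lay on chromosome 7 from 5027431 to 5036733 (mm10), across Zfp865 and parts of its neighbours Ccdc106 and Zfp784. The next strongest lay in the zinc finger gene Zfp810 (chromosome 9, 22276336 to 22281189, enrichment 18.29). Another lay in Spred2, which encodes a negative regulator of Ras and ERK signalling (chromosome 11, 20016084 to 20022135, enrichment 17.88). These peaks were chosen after their values were seen.

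Peak bases lay almost entirely in protein-coding genes. Promoters, exons and introns of these genes held 94.5% ± 0.281 of peak bases, although they make up 39.9% of the sequenced genome. Introns held 71.2% ± 0.926 and exons 22.9% ± 1.21, the latter 7.02 times the exons' share of the genome (3.26%). The 5 kb after gene ends held 4.32% ± 0.129. Promoters, taken as 1 kb on either side of a gene start, held 0.404% ± 0.00266, which was 0.259 times their genome share. Intergenic sequence was the background measured in the same way: 0.0432% ± 0.0152 of its bases lay in peaks, against 30.9% ± 3.18 of exonic and 8.98% ± 1.51 of intronic bases.

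Along genes the mark was lowest at the start and higher towards the 3′ end. Over the 14148 protein-coding genes of 10 kb or longer, 3.27% ± 0.738 of the bases in the first of 10 equal segments of the gene body lay in peaks. This share rose to 15.3% ± 2.35 in segment 3, 21.99% ± 2.69 in segment 6 and 27.8% ± 3.19 in the last segment. It was 14.6% ± 2.22 in the 5 kb after the gene end and 4.26% ± 0.622 in the 5 kb before the start. These flanks were not cleared of neighbouring genes, so peaks in those genes count there too. In the territory of 5 kb after gene ends, which leaves out protein-coding genes, 7.02% ± 1.30 of bases lay in peaks. That territory was drawn for protein-coding genes of any length. The last segment exceeded the first by a factor of 8.61 ± 0.969, a difference larger than the spread between replicates at both positions. With a minimum length of 30 kb the factor was 5.33. In the 6160 genes of 10 kb or longer that were marked, meaning at least 10% covered in each list, coverage rose from 6.60% ± 1.40 in the first segment to 60.1% ± 5.37 in segment 9, and was lower in the last segment in both replicates, at 57.5% ± 5.58.

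**Figure D2:**
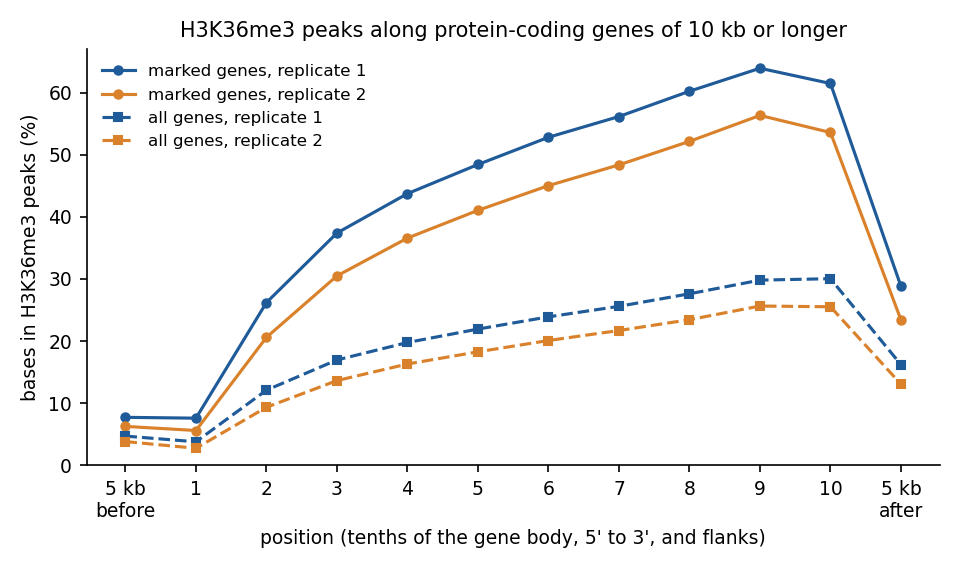
Share of bases in H3K36me3 peaks (%) before, along and after protein-coding genes of 10 kb or longer, for each replicate list, over all 14148 genes (squares, dashed) and over the 6160 marked genes (circles). The flanks were not cleared of neighbouring genes. Over all genes the last segment (27.8% on average) lies above the first (3.27%), and in marked genes segment 9 (60.1%) lies above the last (57.5%) in both replicates.

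A gene was called marked when at least 10% of its body lay in peaks in each replicate list. Of 20326 protein-coding genes of 2 kb or longer, 8031 (39.5%) were marked, 8525 (41.9%) had no peak base in either list, and 3770 (18.5%) lay between. Marked genes had a median coverage of 45.5% in replicate 1 and 37.7% in replicate 2, and 92.0% of them were covered more in replicate 1, by a median of 6.27 percentage points. The replicates ranked genes alike, with a Spearman rho of 0.975 across genes, which are not independent replicates. Marking varied with gene length. It reached 25.8% of genes of 2 to 5 kb, 48.5% of genes of 10 to 30 kb and 48.0% of genes of 30 to 100 kb, but 16 of the 566 genes of 300 kb or longer (2.83%). The limit is a share of gene length, so a longer gene needs more peak bases to be marked. Genes with no peak base in either list made up 66.35% of genes of 2 to 5 kb. They made up 26.6% of genes of 100 to 300 kb and 39.9% of genes of 300 kb or longer.

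Cell cycle and housekeeping genes had the highest marked shares of the 25 gene lists. All 30 cell cycle genes were marked, with a median coverage of 63.97% ± 3.99. Among them Ncapd2, a condensin subunit, had 86.3% ± 2.89 of its body in peaks. The replicative helicase subunits Mcm2, Mcm5 and Mcm3 had 85.3% ± 1.84, 79.7% ± 0.615 and 77.7% ± 3.99. The lowest members were Pcna, the replication clamp (31.6% ± 7.39), and the mitotic cyclin Ccnb1 (33.6% ± 12.7). Of 46 housekeeping genes 44 were marked, led by the splicing factors Sf3b3 (86.2% ± 4.60), Snrnp200 (85.8% ± 2.13) and Prpf8 (85.6% ± 0.744) and the chaperonin subunit Cct3 (84.3% ± 2.16). The exceptions were X-linked Hprt (5.49% ± 2.39) and Eef1a1 (11.9% ± 3.51), which was below 10% in replicate 2. Of 21 genes for enzymes and binding proteins of H3K36 methylation 18 were marked, including the demethylase Kdm4a (88.1% ± 2.41), Brpf1 (73.98% ± 6.42), Phf1 (66.6% ± 10.6) and the methyltransferases Nsd1 (chromosome 13, 55209782 to 55318325, 61.8% ± 4.02) and Setd2 (chromosome 9, 110532597 to 110618633, 51.3% ± 2.31). Phf19 (0.984% ± 1.39) and Kdm2b (10.7% ± 2.70, and 8.78% in replicate 2) were among those not marked. Against 10000 random lists matched on gene length, the median of each of these 3 lists lay at percentile 100.

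Genes for the mesenchymal extracellular matrix were marked in 25 of 28 cases, against 40.0% on average in length-matched random lists, with a median coverage of 41.0% ± 5.55 (percentile 100). The fibrillar collagen gene Col1a1 (chromosome 11, 94936224 to 94953042) had 83.2% ± 2.15 of its body in peaks. Col6a1 had 82.7% ± 1.08, the fibronectin gene Fn1 81.3% ± 4.64, and the laminin gene Lamb1 75.5% ± 2.00. The proteoglycan gene Dcn (1.52% ± 0.279) and Col14a1 (0.719% ± 0.158) were the lowest. Of 23 cartilage and bone genes only Col2a1, the main cartilage collagen (56.9% ± 7.98), and Col10a1 (14.4% ± 2.91) were marked, and Col10a1 overlaps another protein-coding gene and was no longer marked when only peaks with a q-value of 0.01 or lower were used. Col9a2 had 22.9% of its body in peaks in replicate 1 and 5.41% in replicate 2, and the bone regulator Runx2 had 7.17% ± 2.70. Cnmd and Dmp1 had no peak. The median of the cartilage and bone list lay at percentile 30.5.

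Facial signalling genes were marked in 21 of 33 cases, against 36.8% in random lists, with a median coverage of 25.7% ± 4.85 (percentile 99.9). The platelet-derived growth factor receptor genes Pdgfra (chromosome 5, 75152292 to 75198215) and Pdgfrb had 73.1% ± 3.85 and 60.2% ± 4.60 of their bodies in peaks, Tgfb3 56.9% ± 8.93 and the hedgehog receptor gene Ptch1 51.6% ± 6.08. The ligand genes Fgf8 and Edn1 had no peak in either replicate. Genes of orofacial clefts and craniofacial syndromes were marked in 20 of 32 cases (percentile 99.5), led by the histone methyltransferase gene Kmt2d (chromosome 15, 98831669 to 98871204, 84.7% ± 1.70), Tcof1 (80.1% ± 6.14), Eftud2 (76.8% ± 5.22) and X-linked Flna (67.8% ± 2.38). Mafb and Pax9, which encode transcription factors, had no peak.

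Transcription factor genes of the facial mesenchyme were seldom marked. Of 44 such genes 6 were marked (13.6%), against 31.5% in length-matched random lists, 28 had some coverage below the limit in at least 1 list, and 10 had no peak. Snai1 (chromosome 2, 167538195 to 167542814) had 51.2% ± 13.2 of its body in peaks, Msx1 (chromosome 5, 37820485 to 37824583) 44.5% ± 11.7, Alx4 44.0% ± 2.74 and Prrx1 29.2% ± 4.62. Satb2, needed for palate formation, had 6.72% ± 3.16, and Dlx5 had 9.90% in replicate 1 and no peak in replicate 2. Twist1, Dlx1 and Barx1 had no peak in either list. The median coverage of the list, 4.54% ± 2.65, lay at percentile 92.7 of random lists, and at 98.7 once genes that overlap another protein-coding gene were left out. The share of marked members, a statistic chosen after the data were seen, instead lay at percentile 0.235. None of the 38 Hox genes had a peak, Hoxa2 included. Random lists of their lengths were marked in 32% of cases.

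Lists for other cell types and control lists had few marked members. Peaks were called from whole tissue, so a mark carried in only a small part of the cells may be missed. Low coverage therefore does not show that a gene lacks the mark in the cells that use it. Of 25 epithelial genes 1 was marked, Esrp2 (44.5% ± 6.64), which overlaps another protein-coding gene. Dsp, a desmosomal gene, had 8.68% ± 2.77, Tfap2c 7.91% ± 8.06, Itgb4 7.17% ± 1.88 and Irf6, a gene of periderm and palate, 3.24% ± 0.699. Dsp and Tfap2c passed 10% in replicate 1 only. Among named genes of the lists in this paragraph, so did the glial genes Erbb3 (21.1% against 4.85% in replicate 2) and S100b (19.4% against 2.60%), the muscle gene Klhl41 (14.7% against 3.46%) and the red blood cell gene Alas2 (10.03% against 2.41%). No member was marked among 20 neuronal genes (Tubb3 highest, 5.87% ± 4.05), 20 skeletal muscle genes (Klhl41 highest, 9.07% ± 7.94), 17 liver genes or 15 germ cell genes (Dazl highest, 1.65% ± 0.462). A single member was marked in each of 5 further lists. These were Egfl8 of 12 glial genes (81.9% ± 0.270), Eng of 14 endothelial genes (17.6% ± 4.99), Cx3cr1 of 13 macrophage genes (17.7% ± 1.40), Opn1sw of 13 photoreceptor genes (20.2% ± 6.01) and Tfrc of 12 red blood cell genes (39.5% ± 5.33). All of these except Tfrc, the transferrin receptor gene, overlap another protein-coding gene, so their coverage cannot be assigned to them alone. All 1303 olfactory and vomeronasal receptor genes and all 9 replication-dependent histone genes of 2 kb or longer had no peak. Most of these lists had a median of 0, and many random lists did too, so no list lay below the random range by its median when matched on length. The percentiles of these medians ran from 3.57 for endothelium to 50 for the receptor genes, with 3.66 for neurons, 34.8 for epithelium, 37.2 for replication-dependent histones and 41.2 for Hox genes. Against random lists not matched on length the receptor list alone lay below the range. By the share of marked members, a statistic added after the data were seen, 15 lists lay in the lowest 2.5% of their random lists. They were the facial transcription factor, Hox, and cartilage and bone lists, the epithelial, neuronal, glial, muscle, endothelial, red blood cell, macrophage, liver, germ cell, photoreceptor and receptor lists, and the replication-dependent histones.

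**Figure D3:**
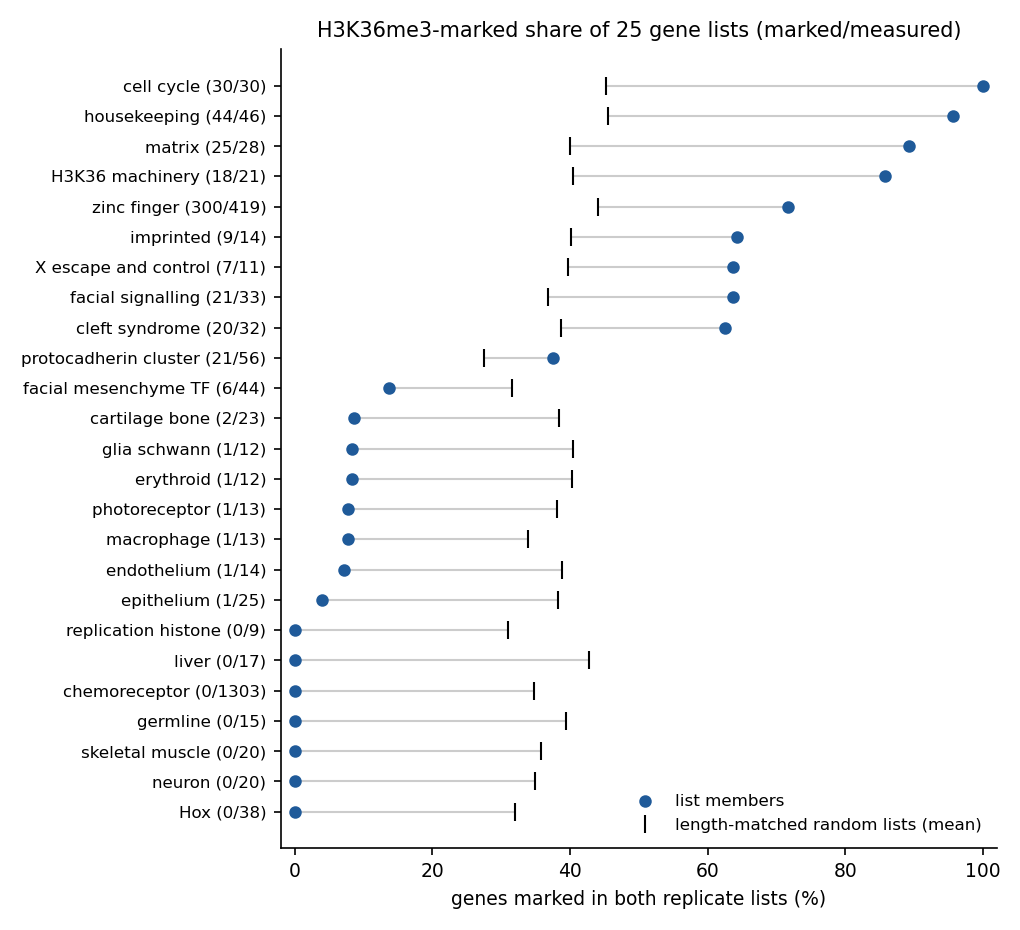
Share of genes marked in both replicate lists (%, circles) for 25 gene lists fixed beforehand, with marked and measured members in brackets, and the mean share in length-matched random lists (bars). All cell cycle genes (30 of 30) and no Hox genes (0 of 38) were marked.

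Zinc finger genes were marked more often than random lists of their lengths. Of 419 measured members 300 were marked (71.6%), against 44.1% in length-matched random lists. Their median enrichment load, the authors' enrichment summed over peak bases and divided by gene length, was 1.52, against 0.168 in random lists (percentile 100). The load rises with coverage as well as enrichment, and its median was higher in the housekeeping (3.29), cell cycle (2.82), H3K36 machinery (2.22) and matrix (1.78) lists, also at percentile 100. Zinc finger genes of this list were 8 of the 10 genes of 5 kb or longer with the highest load. Zfp90 (chromosome 8, 106415327 to 106426598) had a load of 13.3 ± 1.22 and Zfp606 one of 11.3 ± 0.816. Zfp68, Zfp865, Zfp110, Zfp335, Zfp146 and Zfp518b followed with 9.39 ± 1.89, 9.17 ± 0.895, 8.94 ± 0.679, 8.59 ± 3.48, 8.30 ± 0.384 and 8.24 ± 2.33. Repin1, another zinc finger gene, had 9.0 ± 1.58, and Polrmt, the mitochondrial RNA polymerase gene, 8.28 ± 1.42. By coverage the highest members were Zfp869 (97.8% ± 3.17), Zfp335 (88.2% ± 2.43) and Zfp110 (88.0% ± 0.738). The load gives every base of a peak the value of the whole peak, so it has no resolution within peaks.

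Imprinted genes were marked in 9 of 14 cases (percentile 95.6), with Igf2r at 57.1% ± 6.84, Zrsr1 at 53.8% ± 11.9, Impact at 53.4% ± 4.69 and Peg3 at 46.8% ± 4.67. Dlk1 and Ndn had no peak. Clustered protocadherin genes on chromosome 18 were marked in 21 of 56 cases (percentile 19.1 by the median, and 95.2 by the share of marked members). All 21 were the gamma genes, such as Pcdhga3 (49.1% ± 3.4), whose annotated spans overlap and end together, and none of the 13 alpha or 22 beta genes was marked.

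Within the 8031 marked genes exons were covered more than introns. Peaks held 55.6% ± 4.69 of exonic bases and 32.3% ± 4.59 of intronic bases, a ratio of 1.73 ± 0.101. The ratio was 1.66 in replicate 1 and 1.80 in replicate 2, above 1 by more than the spread between replicates.

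Genes on the X chromosome were marked less often than autosomal genes. Both lists marked 97 of 791 X-linked genes (12.3%) and 7934 of 19384 autosomal genes (40.9%). By single lists the shares were 14.6% ± 2.59 on X and 43.0% ± 2.67 on autosomes. Marked X-linked genes also had a lower median coverage, 24.5% ± 5.14 against 41.8% ± 5.57. The difference in each measure exceeded the spread between replicates. Among autosomes the marked share ran from 31.2% on chromosome 14 to 50.8% on chromosome 8. Of 11 X-linked genes listed beforehand 7 were marked (percentile 96.9, and 97.96 when genes that overlap another protein-coding gene were left out of the random lists). This list was picked as genes that escape X inactivation and controls, so it does not represent X-linked genes at large. Its marked members included Flna, the highest (67.8% ± 2.38), Kdm5c (54.8% ± 3.45), Eif2s3x (45.7% ± 0.234) and Ddx3x (41.2% ± 4.46). Msn (1.06% ± 0.678) and Kdm6a (4.29% ± 0.202) had little coverage. Escaping genes and controls were not compared. None of 151 Y-linked genes was marked. Embryos of both sexes were pooled, so only part of the cells carry a Y chromosome. How well reads could be placed on Y genes was not measured. The lack of marked genes therefore does not show that the mark is absent from Y.

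**Figure D4:**
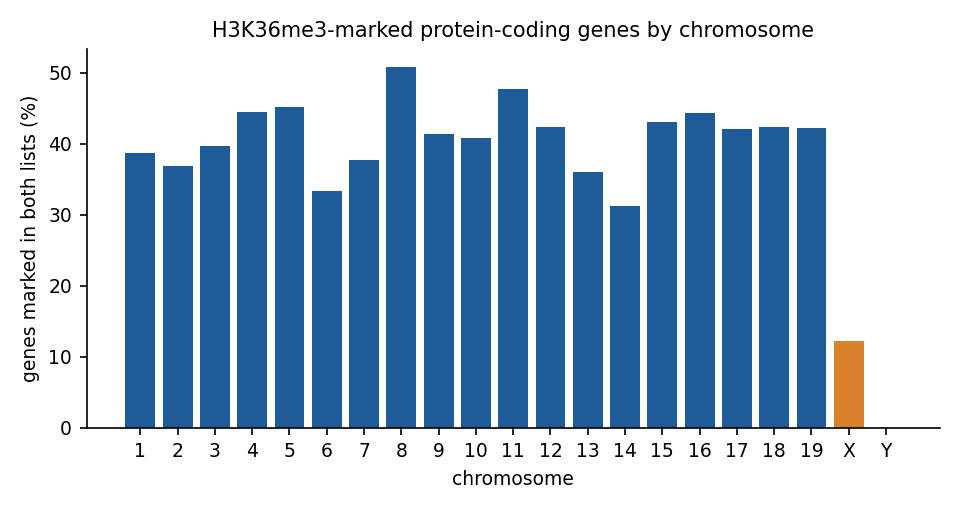
Share of protein-coding genes of 2 kb or longer marked in both replicate lists (%, bars from 0), by chromosome. Autosomes lie between 31.2% and 50.8%, the X chromosome at 12.3% and the Y chromosome at 0%. Embryos of both sexes were pooled, so only part of the cells carry a Y chromosome.

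The largest coverage differences between replicates were in genes covered more in replicate 1. Tefm had 53.2% of its body in peaks in replicate 1 and 19.5% in replicate 2, and Stac3 43.9% and 11.2%. Trmt61a, B230104I21Rik and Tmem126a followed, with 50.95%, 46.7% and 48.9% in replicate 1 against 19.9%, 16.6% and 18.9% in replicate 2. In the other direction the largest difference was in X-linked Cfp, with 8.34% in replicate 1 and 29.99% in replicate 2. Pced1a, Fbxo5, Serp1 and Tsen34 had 33.1%, 45.2%, 39.5% and 46.2% in replicate 2 and 19.4%, 33.5%, 28.4% and 35.4% in replicate 1.

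Replicated peaks merged across gaps of up to 3 kb formed 23354 stretches, of which 428 were 50 kb or longer. The longest ran for 155.3 kb over Ncor1, a nuclear receptor corepressor gene, and Ttc19 (chromosome 11, 62283192 to 62438458), with 59.8% of its bases in peaks. A stretch of 131.2 kb covered Mtor, Exosc10 and Angptl7 (chromosome 4, 148452259 to 148583468). Wdfy3, Depdc5 and Vps13d held stretches of 130.7, 124.4 and 120.9 kb. Only 88 stretches lay farther than 10 kb from any annotated gene. The longest of these was 6.36 kb (chromosome 5, 104581069 to 104587424), 58.5 kb from the nearest protein-coding gene, BC005561. The others of the 5 longest lay on chromosomes 7 (5.44 kb), 17 (3.51 kb), 12 (3.43 kb) and 19 (3.35 kb).

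Some of the genes named here overlap another protein-coding gene, and their coverage is uncertain for that reason. Besides those said to overlap, they are Alx4, Runx2, Tubb3, S100b, Alas2, Sf3b3, Zfp335, Zfp865, Repin1, Phf1, Kdm2b, Tgfb3, Pax9, Zrsr1, Irf6, Hoxa2, B230104I21Rik, Pced1a, Serp1 and Tsen34.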

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

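No test was run in this part, and the genes and peaks it names were chosen after their values were seen. Both results are signals in data that the comparisons left out. No control samples were used here, and no matched background was measured for either count.

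Long non-coding genes lie outside the protein-coding genes of the comparisons. Of 4098 such genes of 2 kb or longer that lie 5 kb or more from any protein-coding gene, 33 (0.805%) were marked in both replicate lists. Among protein-coding genes of 2 kb or longer, which were not chosen by distance from others, 39.5% were marked. Snhg17, a small nucleolar RNA host gene, had 75.9% ± 2.28 of its body in peaks (SD, n = 2), and Mir17hg, the host of a microRNA cluster, 66.9% ± 2.85. Malat1 had 46.3% ± 6.17, and X-linked Ftx 20.9% ± 3.93. In an imprinted region of chromosome 12 the host gene Mirg (109729764 to 109749460) had 53.6% ± 7.56, and Meg3 (109541001 to 109571726) 45.0% ± 8.14. Gm26906, on the opposite strand inside the span of Meg3, had 81.8% ± 21.3, and since peaks carry no strand its coverage cannot be assigned to it. The protein-coding gene Dlk1 of the same region had no peak. No explanation was tested.

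The replicated list held 17 peaks on contigs outside the assembled chromosomes, which the comparisons left out. Of these, 9 lay on a contig placed on X, and 8 of the 9 were in Vamp7 or Tmlhe, with enrichment from 2.01 to 3.17 over the contig. The strongest 2 peaks lay on separate contigs placed on chromosome 4, with enrichment of 11.81 and 7.41. The other 6 lay on 3 unplaced contigs, with enrichment from 1.21 to 2.84. No explanation was tested.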

How the results depend on the processing

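The share of members marked and the X comparison without predicted genes and chemoreceptors were alternatives chosen after the data were seen, as was counting the gamma protocadherins as 1 locus. By the share of members marked, the percentile of the facial transcription factor list turned from 92.7 to 0.235, and the percentile of the clustered protocadherins from 19.1 to 95.2. No other result reversed under the alternatives run. The cause of a change was not tested unless it is stated.

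The count of 8031 marked genes ranged from 5724 (coverage of at least 25%) to 9045 (at least 5%), which follows from the limit itself, and was 8070 and 8831 with a single replicate. The number of gene lists above the random range was 7, and 9 without genes that overlap another protein-coding gene. Leaving out those genes left fewer than 3 protocadherins, so that list gave no value.

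With only peaks of q 0.01 or lower, the mean replicate overlap of peaks went from 71.1% to 70.8%, the Jaccard index of covered bases from 59.5% to 58.7% and peak retention in the replicated list from 66.1% to 69.7%. The replicate agreement across genes went from a rho of 0.975 to 0.971, and the difference of X against autosomes from -28.7 to -29.3 percentage points. Retention was 68.6% with an enrichment of at least 2. Overlap was 76.5% with any shared base and 43.3% with 50% of both peaks, which follows from the rule. With equal numbers of the strongest peaks it was 72.1%, and the Jaccard index 60.6%. Random placement within annotated genes raised the overlap after random placement from 6.66% to 13.1%.

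In the pooled list the genomic territory of protein-coding genes held 94.2% of peak bases and exons 21.3%, and 0.0610% of intergenic bases lay in peaks. The last segment of genes exceeded the first by a factor of 5.33 with a minimum of 30 kb. The replicate agreement across genes had a rho of 0.982 with a minimum of 10 kb, and the ratio of exon to intron coverage 1.49 without first exons and introns. Lists below the random range numbered 0, and 1 with unmatched random lists and 15 by the share of members marked. The X difference was -24.9 points with coverage of at least 25%, -34.3 with genes of 10 kb or longer, -31.96 without predicted genes and chemoreceptors, and -28.45 to -28.34 with a single replicate.

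Of 153 named genes 69 were marked. The call of Col10a1 was lost with the stricter q-value. Calls were gained by Col9a2, Kdm2b and Cfp in the replicated list, by Eef1a1 without the first 1 kb, by Cfp without replicate 1 and by 9 genes without replicate 2, where a single list had to pass. Depth is unknown, so its limits could not be computed.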

Other observations

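The coverage test of marked X-linked genes and the limit to segments 2 to 9 of the gene body were chosen after the results were seen. Of the Y-linked genes of 2 kb or longer, Ddx3y had 4.77% ± 2.98 of its body in peaks (SD, n = 2) and Kdm5d 2.03% ± 2.17, while their neighbour Eif2s3y had no peak. These genes were chosen after their values were seen. With embryos of both sexes pooled, the lack of a peak in a Y-linked gene does not show that it lacks the mark. Among the clustered protocadherins of chromosome 18 the mark lay in the gamma cluster (37661793 to 37841873), where the median gene coverage was 46.3%. In the alpha cluster 10 of 13 genes had no peak, and in the beta cluster 17 of 22, with 10.8% as the highest coverage. The gamma genes overlap, and counted as 1 locus the list had 1 of 36 members marked (percentile 25.4).

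Zinc finger genes carried a higher enrichment load than random lists, with a median of 1.52, though the housekeeping, cell cycle, H3K36 machinery and matrix lists had higher medians (1.78 to 3.29). Against 10000 random lists matched on GC content, whose typical median was 0.0620, the list lay at percentile 100, which argues against GC content as the whole cause. Shared reads between similar genes were examined in part, on the 131 members with at least 99% of their transcript 32-mers found in no other gene. Their median load was 1.71, against 0.132 in random lists (percentile 100), and the other 288 members had 1.30. The 32-mers came from annotated transcripts, while 71.2% of peak bases lay in introns, and the random lists were not filtered alike. The check therefore cannot decide on reads shared through introns or intergenic sequence. No biological explanation was tested.

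Exons of marked genes were covered more than introns. Within 7710 genes the median difference was 16.70 percentage points, which argues against long introns of weakly covered genes as the whole cause. Windows of 1 kb with at least 50% exonic bases were compared with windows without exon in 5 classes of GC content, and the lowest ratio was 2.04. These windows were not matched on position along the gene, so the ratio also carries any effect of position. Position along the gene met the limit set beforehand for it as a cause. That limit was a lowest ratio of at most 1.1 over segments 2 to 10 in a replicate. The ratio was 1.085 in the last segment of replicate 1 and 1.12 in replicate 2. Exons there were covered little more than introns, so that segment holds little excess to explain. Meeting the limit therefore does not show position to be the cause of the excess elsewhere. In segments 2 to 9, a range chosen after this result was seen, the lowest ratio was 1.400. That value argues against position as the whole cause in those segments. In the first segment exons were not covered more (0.849 and 0.962). The segment ratios sum bases over genes, so long introns of weakly covered genes can still lower their intron side. The within-gene difference was not split by segment, so no test held gene and position fixed together. No biological explanation was tested.

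X-linked genes were marked less often than autosomal genes, 12.3% against 40.9%. Autosomal genes weighted to the lengths of X genes had 39.8% marked, which argues against gene length. If X only held fewer transcribed genes, the marked ones would be covered like autosomal genes. Among genes with at least 10% coverage in a list, the median on X minus that on autosomes, weighted to X lengths, was -21.92 ± 2.26 percentage points (SD, n = 2), which argues against fewer transcribed genes as the whole cause and leaves weaker transcription of X genes open. A lower dose, with 1 active copy per cell, cannot be told apart from other causes, because scaling autosomal enrichment for it, which gave 28.87% marked, rests on an assumed scale. No other biological explanation was tested.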
